A study of Gallus gallus with 17 samples.

How the data were processed

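Gene expression was measured in adipose tissue of male chickens of 3 genetic lines on 17 Affymetrix chicken genome arrays, with 1 array per sample. The labels place 6 arrays in a broiler line, 5 in the line Fayoumi M 5.1 and 6 in the line Leghorn GHs 13. All samples were taken at 3 weeks of age. The labels call the arrays of a line biological replicates and do not say how each sample was taken, so p-values measure the spread between these samples. The number of arrays limits the precision.

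The deposited table holds 1 log2 expression value per probe set and array, as normalized by the authors. A probe set is a group of short probes that report on 1 transcript. R 2.13.2, RMA and GCRMA are named in the submitters' processing notes, without saying which of RMA and GCRMA made the values. The log2 scale and the normalization between arrays were read from the deposited values themselves, which run from 2.26 to 16.2 and have medians between 2.48 and 2.59 on the 17 arrays. The lowest value is shared by 36.1% of all values, so a difference against a line at that value is compressed. Scanner images, probe sequences and probe-level intensities were not used here.

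Of the 38535 probe sets, 37693 are designed on chicken transcripts and entered the tests. The remaining 96 hybridisation and labelling controls, 57 reporter probe sets and 689 probe sets named after sequence accessions were left out of the tests. Background was taken as the 95th percentile of 80 blank and reporter probe sets, 2.29 on the log2 scale. By that measure 51.3% of the chicken probe sets lay above background on all 17 arrays and 25.0% on none. Gene symbols came from the platform annotation and were updated by gene number through the NCBI RefSeq gene table of assembly bGalGal1.mat.broiler.GRCg7b, which was used for names alone. Of 27178 probe sets with 1 annotated symbol, 26863 were found there by gene number. In all, 27166 chicken probe sets carried 1 symbol, 177 carried several and 10350 carried none; probe sets with several were not named. Several probe sets can report on 1 gene, and the text says where they differ.

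Differences between lines were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values. One model with the line as its only factor was fitted to all 17 arrays, with lmFit, contrasts.fit and eBayes at default settings. Each contrast was adjusted by Benjamini-Hochberg over the 37693 chicken probe sets, and an adjusted p under 0.05 in the two-sided moderated test counted as a change. All adjusted p-values per gene are limma's. Group values are given as mean ± SD of the log2 values, and differences with limma's standard error (SE). Fold changes are 2 raised to the log2 difference. Where a line was at or below background on all its arrays, the fold is a bound against the lowest signal above background on each array. Elsewhere, where most arrays of the lower line were at background or at a value that another array shares within 0.001, levels are given without a fold, a choice made after the values were seen. The overlap of both comparisons against broiler was set beside 100 simulated pairs of unchanged groups sharing the same broiler arrays.

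The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Genes were named by this rule, per comparison. The 6 genes with the largest difference in each direction were taken among changed probe sets with no overlap between the arrays of the lines, a mean in the higher line at or above the median of all probe sets and 1 symbol not starting with LOC. From each pathway list the 2 members, and from each marker list the 1 member, with the smallest adjusted p were added, whether past the threshold or not. The genes changed in both leaner lines against broiler were to be named likewise. Genes outside this rule are said to be chosen after their values were seen.

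The 26 lists cover mitochondrial fatty acid oxidation, peroxisomal fatty acid oxidation, lipolysis and lipid droplets, fatty acid synthesis and desaturation, fatty acid uptake and triglyceride synthesis, cholesterol synthesis and uptake, adipocyte differentiation and adipokines, glycolysis and glucose entry, the tricarboxylic acid cycle, the mitochondrial respiratory chain, branched-chain amino acid and ketone catabolism, insulin and growth factor signalling, extracellular matrix, the cell cycle, interferon-stimulated genes and antigen presentation. They also cover markers of macrophages, T lymphocytes, B lymphocytes, erythrocytes, skeletal muscle, smooth muscle and pericytes, endothelium, mesenchymal progenitors and epithelium with mesothelium and liver, and immediate early genes. Each of 13008 genes was represented by its probe set with the highest mean. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the 26 lists of a comparison. Counts of changed members are given over all probe sets and adjusted over the list alone. HINTW, a gene of the female-specific W chromosome, served to check the sex label, and the highest values of its 2 probe sets on any array were 2.26 and 2.31.

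The limma step was tested on simulated data made from the real arrays' means and spread, with 200 probe sets shifted by known amounts among 37693. For Fayoumi against broiler it recovered 52.2%, 85.1% and 97.0% of shifts of 1, 2 and 4 on the log2 scale, and 3.11% of its calls were false. For Leghorn against broiler the shares were 55.2%, 79.1% and 95.5%, with 6.71% false, and for Fayoumi against Leghorn 41.8%, 79.1% and 93.9%, with 8.92% false. A list shifted by 1 was called in 20 of 20 draws in each comparison over 13008 genes, and unshifted lists were called in 0, 2 and 2 of 500 tests, in the same order. In both of these tests the probe sets or genes were drawn independently of each other, from normal noise without a lowest value. These draws therefore cannot show how often a list of correlated genes is called falsely. Nor can they show how often the limma step calls falsely where many probe sets differ together between arrays.

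Alternatives covered quantile normalization, centring on array medians, a filter leaving out the dimmest 40% of probe sets, a trended robust variance model, array weights, the replicate number as a block, only the lines compared in the fit, a minimum log2 difference of 1, the mean over all probe sets of a gene, a correlation estimated per list, fry, and each array left out in turn. Alternatives chosen after seeing the data left out the arrays labelled broiler 1 and Leghorn 2, left out 5 arrays that stood apart on the first principal component or carried them as a covariate, and combined these. No 2 arrays held identical values, and the correlation between arrays lay between 0.920 and 0.997. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.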

Results

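Adipose gene expression was compared between broiler chickens, a line bred for fast growth and meat, and the Fayoumi and Leghorn lines, which are leaner. The stated aim of the study was to find pathways associated with leanness. The values are log2 expression on 17 arrays, 6 from broiler, 5 from Fayoumi and 6 from Leghorn, all from males at 3 weeks of age. Between 56.0% and 59.1% of the chicken probe sets lay above background on an array.

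The arrays did not group by line alone. The first principal component carried 54.0% of the variance over 14809 probe sets, and on it 5 arrays stood apart, labelled broiler 2, 3 and 4 and Leghorn 3 and 6. Their scores lay between 0.212 and 0.477, and those of the other 12 arrays between -0.194 and -0.126. The difference between 3' and 5' probe sets of ACTB, a measure of RNA integrity and labelling, was 1.49 to 1.92 on these 5 arrays and 1.91 to 2.70 on the other 12. A position between broiler, at 0, and Leghorn, at 1, was taken for the arrays labelled broiler 1 and Leghorn 2 over 24 probe sets higher in broiler and 25 higher in Leghorn by over 2 on the log2 scale on the other 10 arrays of both lines. For each of those 10 it was taken over the probe sets that passed this without the array itself, 24 to 29 higher in broiler and 25 to 33 higher in Leghorn. The array labelled broiler 1 lay at 1.03 and the array labelled Leghorn 2 at 0.0841, against -0.00256 to 0.0685 on the other 5 broiler arrays and 0.967 to 1.03 on the other 5 Leghorn arrays. The comparisons are given with the arrays as labelled. Beside each count stands the count without these 2 arrays, an alternative chosen after seeing the data, because they lay with the other line.

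**Figure D1:**
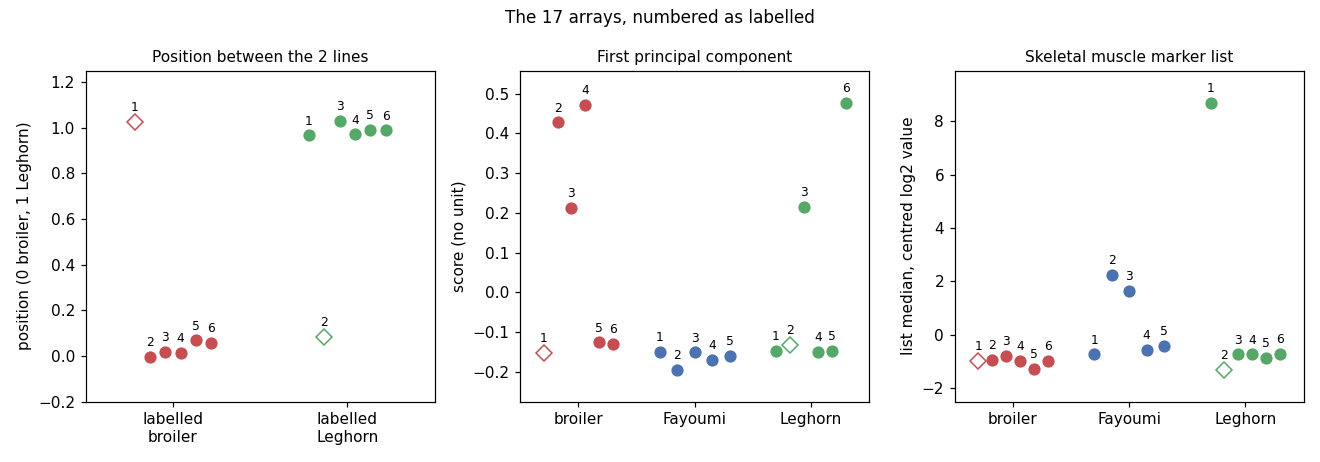
Left, the position of each broiler and Leghorn array between the 2 lines (no unit, 0 for broiler and 1 for Leghorn); middle, the first principal component score of all 17 arrays (no unit); right, the median of the skeletal muscle marker list on each array (log2, each gene centred). Each point is 1 array with its replicate number, open diamonds are the arrays labelled broiler 1 and Leghorn 2, and the array labelled Leghorn 1 lies at 8.69 in the muscle list.

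Against broiler, Fayoumi adipose tissue showed very large differences at single probe sets, lower levels of the respiratory chain and cell cycle lists and a higher level of the insulin and growth factor list. With an estimated correlation between genes none of these lists was called (adjusted p = 0.910, 0.910 and 0.833). Of 100 ways to split the arrays of both lines into groups, the real one included, 41 gave as many called lists or more. DDTL, a relative of the cytokine-like tautomerase MIF, was at 8.38 ± 0.15 (SD, n = 5) in Fayoumi and 3.17 ± 0.38 (SD, n = 6) in broiler, 37.0-fold higher (SE of the log2 difference 0.18, adjusted p = 2.28e-10). CANX, the gene of the endoplasmic reticulum chaperone calnexin, was at 3.98 ± 0.86 in Fayoumi and 10.17 ± 0.71 in broiler, 73.3-fold lower (SE 0.40, adjusted p = 7.99e-07). The second probe set of CANX did not change in that direction. VLDLR, a receptor that takes up triglyceride-rich lipoproteins, was 1.91-fold higher in Fayoumi, at 12.05 ± 0.13 against 11.12 ± 0.31 (SE 0.17, adjusted p = 0.0215).

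The other genes with the largest rise in Fayoumi were FZD6, a Wnt receptor (13.0-fold, adjusted p = 0.00238, and adjusted p = 0.0891 without the 5 arrays that stood apart, where the log2 difference went from 3.70 to 3.31), HHLA2, an immune checkpoint ligand (6.50 ± 0.38 against 3.14 ± 0.52, adjusted p = 0.000182), SHQ1, which helps assemble small nucleolar ribonucleoproteins (7.30-fold, adjusted p = 0.00164), and SCTR, the secretin receptor (5.14 ± 0.72 against 2.35 ± 0.02, adjusted p = 1.60e-05). For HHLA2 and SCTR 4 and 5 of 6 broiler arrays were at a shared or background value, so no fold is given. TRMT6, a subunit of a tRNA methyltransferase, was not above background on any broiler array and at least 7.25-fold higher in Fayoumi (adjusted p = 8.41e-06). The largest falls after CANX were in GSKIP, a binding partner of glycogen synthase kinase (40.5-fold, adjusted p = 2.70e-05), and CMTM3, above background on 1 of 5 Fayoumi arrays (2.30 ± 0.09 against 7.29 ± 0.62, adjusted p = 1.38e-07). TNFRSF1B, a receptor for tumour necrosis factor, fell by 4.75 on the log2 scale (SE 0.99, adjusted p = 0.0420), with 4 of 5 Fayoumi arrays above background. TMEM268 was 18.3-fold lower (adjusted p = 2.47e-05). PRTFDC1, a relative of the purine salvage enzyme HPRT, was lower at 2.99 ± 0.45 against 6.24 ± 0.28 (adjusted p = 6.57e-07), with 1 shared value on 3 of 5 Fayoumi arrays. At each of these 12 genes all 5 Fayoumi arrays lay beyond all 6 broiler arrays. Of 20 other probe sets on 11 of the 12 genes, 18 lay above background and 2 changed in the same direction, 1 of SHQ1 and 1 of GSKIP. The second probe set of CANX, for one, was at a mean of 11.50 in Fayoumi and 10.79 in broiler.

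**Figure D2:**
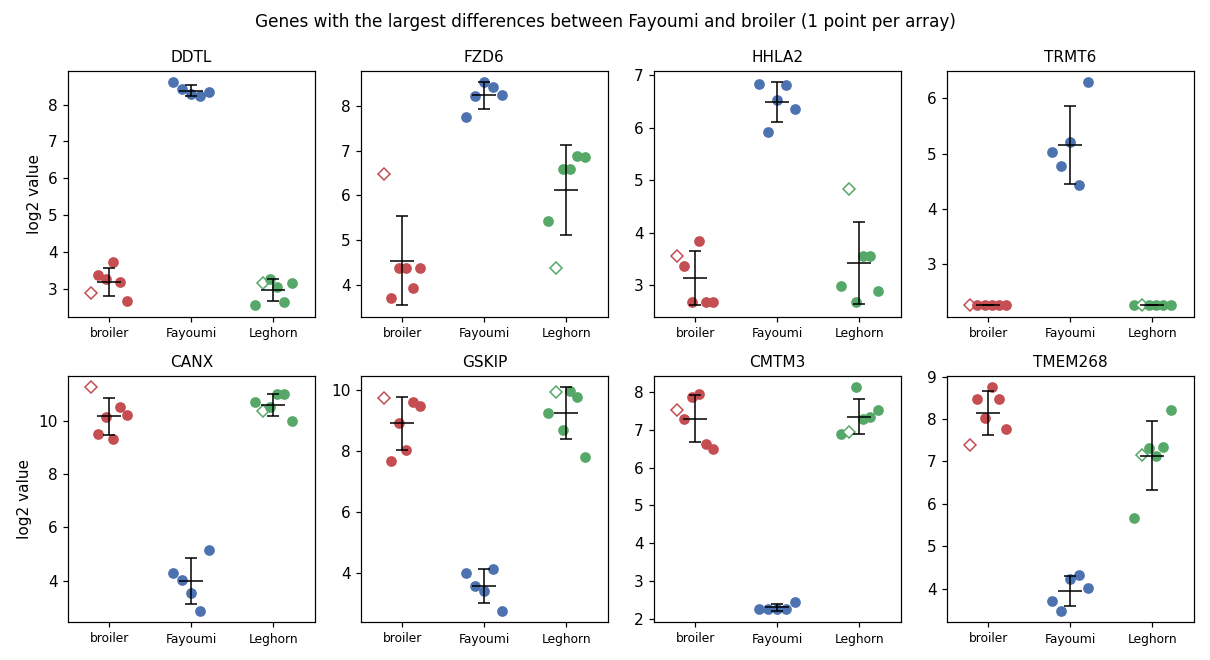
Log2 values of 8 of the genes with the largest difference between Fayoumi and broiler, with 1 point per array, the horizontal line at the mean of a line and bars of 1 SD. Open diamonds are the arrays labelled broiler 1 and Leghorn 2. For DDTL all 5 Fayoumi points lie above all broiler and Leghorn points, and for CANX, GSKIP and CMTM3 all lie below.

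The mitochondrial respiratory chain list fell in Fayoumi, with a median log2 difference of -0.33 over 28 measured members, of which 25 were lower and 3 higher (adjusted p = 9.07e-05, and adjusted p = 0.910 with an estimated correlation). Single members did not pass over all probe sets, while 7 fell and 1 rose adjusted over the list alone. NDUFC2, a subunit of complex I, was at 12.41 ± 0.13 in Fayoumi and 13.11 ± 0.46 in broiler (adjusted p = 0.171). On single arrays the list's median was between -0.37 and -0.11 in Fayoumi, and highest at 0.66 on the array labelled Leghorn 1 and 0.59 on the array labelled broiler 2. Without the 5 arrays that stood apart the call was lost (adjusted p = 0.117, with 1.52e-06 to 0.910 over the 33 alternatives). The cell cycle list fell, with a median of -0.47 and 27 of 33 members lower (adjusted p = 0.00023, and adjusted p = 0.910 with an estimated correlation). On single arrays the cell cycle list's median overlapped between the lines, at -0.50 to 0.42 in Fayoumi and -0.16 to 0.53 in broiler. TYMS, thymidylate synthase, fell by 1.04 (SE 0.20, adjusted p = 0.0261), and 3 members fell adjusted over the list alone.

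The insulin and growth factor signalling list rose by a median of 0.42 over 21 members, 14 of them higher (adjusted p = 0.0119, and adjusted p = 0.833 with an estimated correlation). Single members did not pass over all probe sets, and 3 rose adjusted over the list alone. IGFBP5, which binds insulin-like growth factors, was at 6.96 ± 0.29 in Fayoumi, with a log2 difference of 0.97 that did not pass (adjusted p = 0.0580). This list moved with the arrays that stood apart. Its median lay between -0.64 and 0.07 on those 5 arrays and between -0.00266 and 0.41 on the other 12, and its call was lost with their state as a covariate (adjusted p = 0.146, with 0.00804 to 0.833 over the 33 alternatives). The skeletal muscle marker list rose by a median of 1.28, with 19 of 22 members higher and none called alone, also not adjusted over the list alone (adjusted p = 0.0371, and adjusted p = 0.910 with an estimated correlation). Its median was 2.23 and 1.65 on the arrays labelled Fayoumi 2 and 3 and between -0.73 and -0.42 on the other Fayoumi arrays. The call was lost in 17 of 33 alternatives, among them without the array labelled broiler 1, 5 or 6, Fayoumi 2 or 3, or Leghorn 6, where adjusted p lay between 0.0739 and 0.183. Over all 33 alternatives adjusted p lay between 1.46e-06, without the array labelled Leghorn 1, and 0.910. TNNC1, the slow muscle troponin C, was at 8.91 ± 0.29 in Fayoumi and 5.85 ± 0.87 in broiler (adjusted p = 0.357).

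In the other 22 lists adjusted p lay between 0.0640 and 0.930, the lowest in branched-chain amino acid and ketone catabolism. Members changed singly in 6 of them. BCKDHB, a subunit of the branched-chain keto acid dehydrogenase, fell by 1.19 (SE 0.17, adjusted p = 0.00309), and 2 of the 21 members of its list fell adjusted over the list alone. TALDO1, the pentose phosphate enzyme transaldolase, fell by 0.97 (SE 0.13, adjusted p = 0.00150) as the 1 changed member of 19 in fatty acid synthesis. VLDLR was the 1 changed member of 22 in fatty acid uptake and triglyceride synthesis. Among immune and vascular markers, BF2, a class I histocompatibility gene, rose 5.27-fold (adjusted p = 0.0168), and TIMD4, a macrophage receptor for dying cells, rose 3.09-fold (adjusted p = 0.0141). LMO2, a transcriptional regulator of blood and endothelial cells, fell by 1.11 (SE 0.18, adjusted p = 0.00798), and without the 5 arrays that stood apart the difference was -0.97 and not called (adjusted p = 0.129, with 0.00197 to 0.129 over 31 alternatives). All 5 Fayoumi arrays lay beyond all broiler arrays at these 6 genes. Of the 3 other probe sets of TALDO1 1 changed in the same direction, and none did of the 3 of BF2 and the 1 each of TIMD4 and LMO2. Adjusted over the list alone, 14 of the 26 lists had a changed member, 11 members higher and 20 lower. In the oxidation lists that the study's question concerns, EHHADH, a peroxisomal beta-oxidation enzyme, was at 7.04 ± 0.16 in Fayoumi and 8.40 ± 0.78 in broiler (adjusted p = 0.0907). ECI1 of mitochondrial beta-oxidation was at 9.47 ± 0.16 and 10.24 ± 0.69 (adjusted p = 0.368). Adiponectin (ADIPOQ), a hormone of adipocytes, was at 11.68 ± 0.22 and 12.82 ± 0.46 (adjusted p = 0.0770).

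In all, limma called 269 probe sets in Fayoumi against broiler, 135 higher and 134 lower. Over all chicken probe sets, called or not, 1136 or 3.01% had no overlap between the lines' arrays, where chance gives 0.433%. Without the arrays labelled broiler 1 and Leghorn 2 the count was 686, with 262 of the 269 among them. Leaving out the array labelled broiler 1 alone gave 613, and the count fell to 170 and 171 without the arrays labelled broiler 2 and 4, and to 169, 148, 161 and 174 without the arrays labelled Fayoumi 1, 2, 4 and 5. The call of TNFRSF1B was lost without any 1 of the arrays labelled broiler 2 to 6, Fayoumi 1 to 5 or Leghorn 3 to 5 (adjusted p = 0.0540 to 0.107), of TYMS without broiler 2 to 5 or Fayoumi 1, 4 or 5 (0.0577 to 0.0841), of VLDLR without broiler 3 or 4 or Fayoumi 2 to 5 (0.0507 to 0.0685), of BF2 without Fayoumi 2 or 5 (0.0501 and 0.0524) and of TIMD4 without Fayoumi 2 (0.0501).

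Leghorn against broiler gave lower levels of lipid synthesis lists and no single changed probe set with the arrays as labelled, and the lists were not called with an estimated correlation. Of 100 ways to split the arrays of both lines into groups, the real one included, 70 gave as many called lists or more. The cholesterol synthesis and uptake list fell in Leghorn, with a median log2 difference of -0.64 and 15 of 17 members lower (adjusted p = 0.000456, and adjusted p = 0.592 with an estimated correlation). The fatty acid synthesis and desaturation list fell, with a median of -0.43, 15 of 19 members lower and 2 falling adjusted over the list alone (adjusted p = 0.000456, and adjusted p = 0.592 with an estimated correlation). SQLE, squalene epoxidase of cholesterol synthesis, was at 7.34 ± 1.33 (SD, n = 6) in Leghorn and 8.92 ± 1.14 (SD, n = 6) in broiler (adjusted p = 0.852). ACLY, which makes acetyl-CoA for lipid synthesis, was at 8.67 ± 0.90 and 9.99 ± 0.69 (adjusted p = 0.835).

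The spread of these genes was wide within each line. SQLE was at 10.03 on the array labelled Leghorn 2, above the other 5 Leghorn arrays. DHCR7, the last enzyme of cholesterol synthesis, was at 9.33 ± 0.98 in Leghorn and 10.25 ± 0.49 in broiler (adjusted p = 0.852), and FADS2, a fatty acid desaturase, at 9.99 ± 0.93 and 11.42 ± 0.86 (adjusted p = 0.852). On single arrays the cholesterol list's median was highest at 1.28 and 1.06 on the arrays labelled broiler 2 and 4 and 1.02 on the array labelled Leghorn 2, and lowest at -1.02 on the array labelled Leghorn 1. Both lipid synthesis calls were lost without the 5 arrays that stood apart (adjusted p = 0.577 for cholesterol and 0.125 for fatty acids, with 1.52e-09 to 0.629 and 0.000103 to 0.629 over the 33 alternatives).

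**Figure D3:**
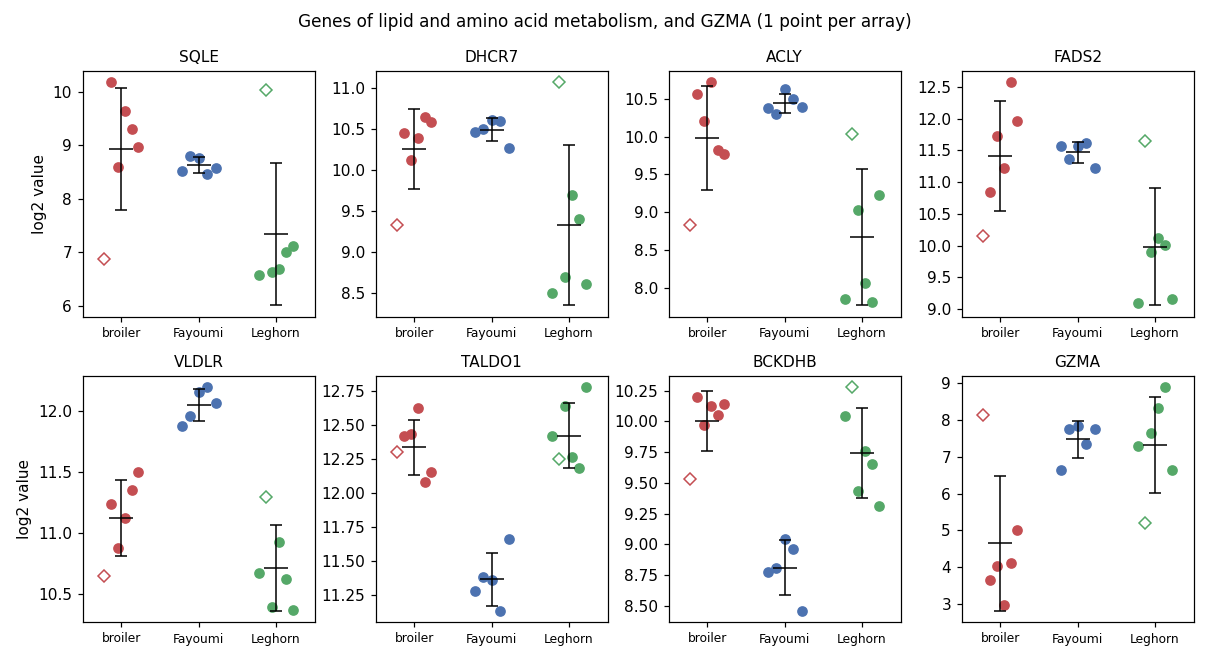
Log2 values of 7 genes of lipid and amino acid metabolism and of GZMA, with 1 point per array, the horizontal line at the mean of a line and bars of 1 SD. Open diamonds are the arrays labelled broiler 1 and Leghorn 2; for SQLE the Leghorn diamond lies at 10.03.

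The cell cycle list fell in Leghorn, with a median of -0.27 and 31 of 33 members lower (adjusted p = 8.83e-05, and adjusted p = 0.592 with an estimated correlation). NUF2, a kinetochore protein, was at 3.84 ± 0.78 in Leghorn, with a log2 difference of -1.16 (adjusted p = 0.852). The skeletal muscle marker list rose by a median of 1.60 with 20 of 22 members higher (adjusted p = 8.83e-05, and adjusted p = 0.618 with an estimated correlation). Its median was 8.69 on the array labelled Leghorn 1 and between -1.30 and -0.72 on the other 5 Leghorn arrays, and the call was lost without that array (adjusted p = 0.518, with 4.66e-06 to 0.629 over the 33 alternatives). TNNC1 was at 7.97 ± 3.11 in Leghorn, with 14.08 on the array labelled Leghorn 1, and 5.85 ± 0.87 in broiler (adjusted p = 0.852). In the other 22 lists adjusted p lay between 0.0646 and 0.950, and adjusted over the list alone fatty acid synthesis was the only list of the 26 with a changed member. The lowest were T lymphocyte markers and epithelial, mesothelial and liver markers, with medians of 0.05 and 0.15 and adjusted p of 0.0646 each. GZMA, granzyme A of cytotoxic lymphocytes, was at 7.33 ± 1.31 in Leghorn and 4.64 ± 1.83 in broiler (adjusted p = 0.835). CPT1A, which admits long-chain fatty acids to mitochondria, was at 6.79 ± 0.76 and 5.47 ± 1.37 (adjusted p = 0.852). The lists of mitochondrial and peroxisomal fatty acid oxidation had medians of -0.03 and -0.15 (adjusted p = 0.950 and 0.122).

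At 0 calls by limma, 1840 of 37693 probe sets had an unadjusted p under 0.05 and the lowest adjusted p was 0.835. That is close to the share of 0.05 that chance gives. Over all chicken probe sets, 7 or 0.0186% had no overlap between the lines' arrays as labelled, where chance gives 0.216%. A trended robust variance model also gave 0, and array weights gave 9. Without the arrays labelled broiler 1 and Leghorn 2 the count was 661, 258 higher and 403 lower in Leghorn, and without the array labelled broiler 1 alone it was 118.

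**Figure D4:**
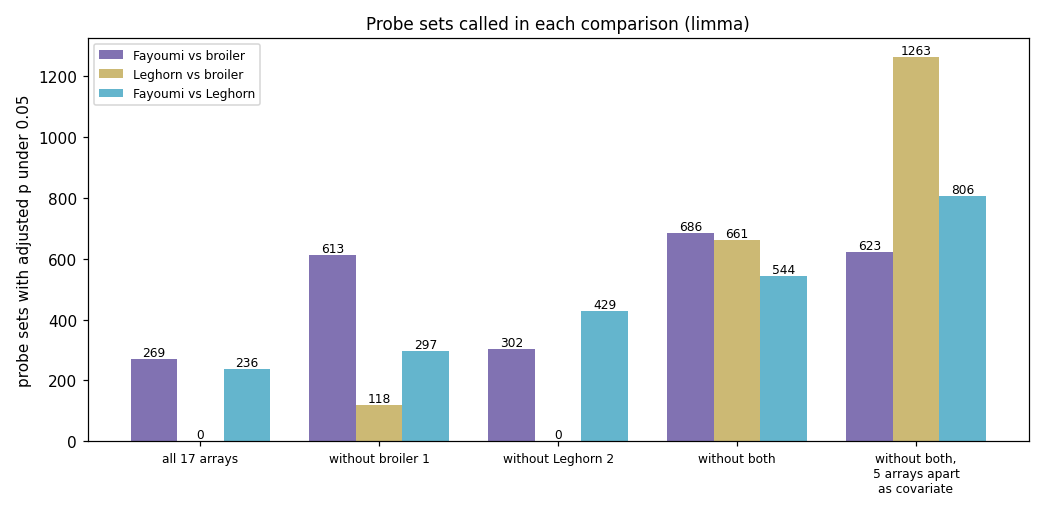
Number of probe sets with an adjusted p under 0.05 by limma in each comparison, with all 17 arrays and without the arrays labelled broiler 1, Leghorn 2 or both, and with the 5 arrays apart as a covariate. Bars start at 0; for Leghorn against broiler they go from 0 with all arrays to 661 without both.

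Fayoumi against Leghorn also showed large differences at single probe sets, and a lower level of the respiratory chain list. With an estimated correlation between genes that list was not called (adjusted p = 0.821). All 100 ways drawn to split the arrays of both lines into groups, the real one included, gave as many called lists or more. SOST, the Wnt inhibitor sclerostin known from bone, was at 10.18 ± 0.71 (SD, n = 5) in Fayoumi and 3.22 ± 0.99 (SD, n = 6) in Leghorn, 125-fold higher (SE of the log2 difference 1.05, adjusted p = 0.00439). Its call was lost with the replicate number as a block, at a log2 difference of 6.88 against 6.96 (adjusted p = 0.0538, with 1.24e-05 to 0.0538 over 31 alternatives). DDTL was at 8.38 ± 0.15 and 2.95 ± 0.30, 43.0-fold higher (SE 0.18, adjusted p = 1.28e-10). CANX was at 3.98 ± 0.86 and 10.60 ± 0.40, 98.7-fold lower (SE 0.40, adjusted p = 3.99e-07), while its second probe set did not change in that direction. RCSD1, a protein that binds actin capping protein, was at 2.86 ± 0.38 in Fayoumi and 9.43 ± 0.52 in Leghorn (SE 0.79, adjusted p = 0.000646), with 4 of 5 Fayoumi arrays at a shared or background value. VLDLR was 2.53-fold higher, at 12.05 ± 0.13 against 10.71 ± 0.35 (SE 0.17, adjusted p = 0.00117).

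Among the 12 genes with the largest differences, DDTL, HHLA2, TRMT6, CANX, GSKIP, CMTM3 and PRTFDC1 also stood among the 12 of Fayoumi against broiler. HHLA2 was 8.45-fold higher and GSKIP 50.9-fold lower (adjusted p = 0.000459 and 1.46e-05). TRMT6 was not above background on any Leghorn array and at least 7.25-fold higher in Fayoumi (adjusted p = 7.90e-06). DIEXF, a factor in ribosome biogenesis, was 20.6-fold higher (adjusted p = 0.0342), and ACSL6, an acyl-CoA synthetase, 7.56-fold higher (adjusted p = 0.00182). PWP1 was 9.36-fold lower (adjusted p = 8.12e-05) with 4 of 5 Fayoumi arrays above background. CMTM3 was at 2.30 ± 0.09 in Fayoumi and 7.35 ± 0.45 in Leghorn (adjusted p = 1.18e-07), and PRTFDC1 at 2.99 ± 0.45 and 6.21 ± 0.30 (adjusted p = 6.16e-07), with the Fayoumi arrays of both as above. At each of the 12 genes all 5 Fayoumi arrays lay beyond all 6 Leghorn arrays. Of the 21 other probe sets on these genes, 18 lay above background and 1, of GSKIP, changed in the same direction.

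The respiratory chain list fell, with a median of -0.35 and 26 of 28 members lower in Fayoumi (adjusted p = 1.52e-06, and adjusted p = 0.821 with an estimated correlation). It was the 1 list called. Single members did not pass over all probe sets, and 1 rose adjusted over the list alone. NDUFB9 of complex I was at 10.74 ± 0.14 in Fayoumi and 11.61 ± 0.49 in Leghorn (adjusted p = 0.223). The list's median was 0.66 on the array labelled Leghorn 1. In the other 25 lists adjusted p lay between 0.0635 and 0.985, and 4 of the 26 had a member changed singly. HSD17B13, a lipid droplet protein, rose 2.42-fold (adjusted p = 0.0423) as the 1 changed member of 13 in lipolysis and lipid droplets. TALDO1 fell by 1.06 (SE 0.13, adjusted p = 0.000646) and BCKDHB by 0.94 (SE 0.17, adjusted p = 0.0193). Adjusted over the list alone, 14 lists had a changed member, 14 members higher and 8 lower. PLIN2, a coat protein of lipid droplets, was at 9.13 ± 0.27 in Fayoumi and 10.82 ± 0.79 in Leghorn (adjusted p = 0.122). IGFBP2, which binds insulin-like growth factors, was at 11.83 ± 0.72 and 8.65 ± 1.31 (adjusted p = 0.0918). MARCO, a macrophage scavenger receptor, was at 3.05 ± 0.11 and 5.59 ± 1.33 (adjusted p = 0.0540).

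In all, limma called 236 probe sets in Fayoumi against Leghorn, 134 higher and 102 lower. Over all chicken probe sets, called or not, 956 or 2.54% had no overlap between the lines' arrays, where chance gives 0.433%. Without the arrays labelled broiler 1 and Leghorn 2 the count was 544, with 225 of the 236 among them, and without the array labelled Leghorn 2 alone it was 429. The call of DIEXF was lost without any 1 of the arrays labelled broiler 3, Fayoumi 1 to 5 or Leghorn 1 and 3 to 6 (adjusted p = 0.0502 to 0.0897), of HSD17B13 without broiler 3, 5 or 6, Fayoumi 1 to 4 or Leghorn 1 to 6 (0.0528 to 0.128) and of BCKDHB without Fayoumi 1, 2 or 5 (0.0560 to 0.0581).

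Genes changed in both Fayoumi and Leghorn against broiler would be those shared by the leaner lines, and 0 probe sets met that with the arrays as labelled, as limma called none in Leghorn. In 100 simulations of unchanged groups against the same broiler arrays the overlap was also 0, and independent lists would share 0. Over all probe sets the log2 differences of both comparisons correlated across genes, which are not independent replicates, at r = 0.502, against a mean of 0.467 in the simulations. Their covariance was 0.0781, against a simulated mean of 0.0310 and highest of 0.124. With broiler replicates 1 to 3 set against Fayoumi and 4 to 6 against Leghorn, the overlap was 0 and the covariance 0.0378, and with these sets exchanged 0 and 0.0795. Without the arrays labelled broiler 1 and Leghorn 2, 241 probe sets changed in the same direction in both, 96 higher and 145 lower. The overlap was 0 in the simulations, which decides nothing, since unchanged groups are bound to leave few calls to share. Independent lists would share 2.10 higher and 4.05 lower, values that take no account of the shared broiler arrays. With the remaining broiler arrays split the same way, 103 and 95 were shared, with covariances of 0.0724 and 0.153. Over all probe sets of this fit the other measures lay within the range of the simulations, with a covariance of 0.137 against a mean of 0.0318 and a highest of 0.153, r = 0.558 against -0.611 to 0.934, and 53.6% of the same sign against a mean of 54.8%.

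The lists not called in a comparison had these adjusted p-values, in the order Fayoumi against broiler, Leghorn against broiler and Fayoumi against Leghorn. For mitochondrial fatty acid oxidation they were 0.395, 0.950 and 0.235, for peroxisomal fatty acid oxidation 0.930, 0.122 and 0.235, and for lipolysis and lipid droplets 0.588, 0.604 and 0.966. Fatty acid uptake and triglyceride synthesis gave 0.395, 0.604 and 0.168, adipocyte differentiation and adipokines 0.930, 0.943 and 0.985, and glycolysis and glucose entry 0.367, 0.943 and 0.271. The tricarboxylic acid cycle gave 0.428, 0.290 and 0.0950, branched-chain amino acid and ketone catabolism 0.0640, 0.943 and 0.0635, and extracellular matrix 0.697, 0.326 and 0.235. Interferon-stimulated genes gave 0.194, 0.128 and 0.730 and antigen presentation 0.830, 0.943 and 0.612. Among cell type markers, macrophages gave 0.696, 0.128 and 0.730, T lymphocytes 0.365, 0.0646 and 0.976, B lymphocytes 0.930, 0.182 and 0.462, and erythrocytes 0.545, 0.943 and 0.610. Smooth muscle and pericytes gave 0.545, 0.943 and 0.637, endothelium 0.930, 0.943 and 0.966, mesenchymal progenitors 0.545, 0.326 and 0.976, and epithelial, mesothelial and liver markers 0.930, 0.0646 and 0.235. Immediate early genes gave 0.588, 0.943 and 0.610. Against broiler in Fayoumi, cholesterol synthesis gave 0.545 and fatty acid synthesis 0.428. Against broiler in Leghorn, the respiratory chain gave 0.943 and insulin and growth factor signalling 0.113. Between Fayoumi and Leghorn, cholesterol synthesis gave 0.168, fatty acid synthesis 0.235, insulin and growth factor signalling 0.235, the cell cycle 0.371 and skeletal muscle markers 0.747.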

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

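Of the tests in this part, those on the label exchange, the mixed RNA, the covariate, the sequence variant, the values shared by arrays and the muscle signal were chosen after the result was seen, and those on other pairs of arrays and on the lowest value were written before. Arrays were singled out where 1 lay far from the others of its line by Dixon's test. This held for 13 of 126 gene and line combinations, for 2 of 73 more without the arrays labelled broiler 1 and Leghorn 2, and for 10 of 78 list and line combinations. Chance gives about 1 in 20 for values without ties. That rate does not hold where most arrays of a line sat at a shared or background value, as for CMTM3, PRTFDC1 and SCTR.

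The array labelled broiler 1 stood apart from the other broiler arrays in FZD6 at 6.49, TNFRSF1B at 3.97, BCKDHB at 9.53, IFI27L2 at 9.49 and the B lymphocyte marker list at 0.57. The array labelled Leghorn 2 stood apart from the other Leghorn arrays in SQLE at 10.03, SOST at 5.15, DIEXF at 7.20 and RCSD1 at 8.41. Their positions between the lines were 1.03 and 0.0841, so each lay with the line it is not labelled as. Against a mix of RNA of both lines, 95.8% and 76% of the probe sets high in the labelled line were at or below the highest array of the other line there. Against the 5 arrays that stood apart as the only reason for 0 calls in Leghorn against broiler, 0 were called with them as a covariate. This cannot exclude that they played a part, since the arrays labelled broiler 1 and Leghorn 2 stayed in that fit. Without the arrays labelled broiler 1 and Leghorn 2, the covariate took the count from 661 to 1263. Against the loss of any 2 arrays as the reason for the 661 without these 2, leaving out the 35 other pairs of 1 broiler and 1 Leghorn array gave at most 60 calls, with a median of 0. A candidate explanation that stays open is an exchange of these 2 labels or samples, and since both the arrays and the test come from the same data it remains a hypothesis, while birds of unlike ancestry within a line were not tested.

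The array labelled Leghorn 1 stood apart in TNNC1 at 14.08 and in the skeletal muscle list at 8.69. It also stood apart in the lists of mitochondrial fatty acid oxidation at 0.42, the tricarboxylic acid cycle at 0.77, lipolysis at -0.66, fatty acid synthesis at -0.95 and adipocyte differentiation at -0.37, and without the arrays labelled broiler 1 and Leghorn 2 in DNAJC3 at 2.61. On it 18 of the 22 measured muscle genes lay over 2 log2 units above the highest other Leghorn array, with ACTA1 at 15.86, MYH1B at 15.62 and MYL1 at 15.51, genes chosen after their values were seen. Of the 22 genes, 10 had a median above background on the 14 arrays other than this and Fayoumi 2 and 3, and 0 are in another list. Against a line difference, 2 of the other 5 Leghorn arrays lay at or below the highest broiler array in the list's median. Against the authors' normalization as the cause, the largest median of any other list on this array was 1.02 in size, while its mean of hybridisation controls was 10.03, below 10.35 to 11.69 on the other 16 arrays. Skeletal muscle in the sample may account for the signal, and no test told muscle tissue from free muscle RNA.

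Some genes were near background in 1 line and high in another, while other probe sets of the same gene did not follow. Over called differences of at least 3 on the log2 scale, the ratio of another probe set's difference to the called one had a median of -0.00245 over 33 pairs (quartiles -0.112 and 0.174), with 4 called in the same direction, while for differences under 1.5 the median was 0.236 over 231 pairs (quartiles -0.0508 and 0.789). The differences of at least 3 pool 23 in Fayoumi against broiler and 19 in Fayoumi against Leghorn. These comparisons share the Fayoumi arrays and many of the probe sets, so the same probe set can be counted in both. The lower line sat at the lowest value of the authors' table on all arrays in 2 of these 42 differences, 4.76%, 1 in each comparison. This misses values that arrays share above it. With those included, most lower-line arrays sat at a shared or background value in 12 of 42, 28.6%, and none did in 15. A floor set by the authors' normalization therefore stays open as a part of the pattern. A candidate explanation is a sequence variant of the line under the probes, and a true difference in one transcript form stays open, since probe sequences were not used here.

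The other single arrays are given as values. The array labelled broiler 3 was apart in SCTR at 2.30 and, without the arrays labelled broiler 1 and Leghorn 2, in UMPS at 2.44. The array labelled broiler 2 was apart in the smooth muscle and pericyte list at 1.40. The array labelled Fayoumi 5 was apart in CMTM3 at 2.45 and in the B lymphocyte list at 0.0246, and the array labelled Fayoumi 4 in PRTFDC1 at 3.76 and MARCO at 3.25. The array labelled Leghorn 4 was apart in the cell cycle list at -0.32. Outside the tests, 9 of 689 probe sets named after sequence accessions lay above background on all 17 arrays and 552 on none, and the highest of them had a mean of 11.2.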

How the results depend on the processing

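The settings without the arrays labelled broiler 1 and Leghorn 2, without the 5 arrays that stood apart, with those 5 as a covariate, and their combinations were chosen after seeing the data, and the others were planned. Across 33 alternatives per list and all those run per gene, 0 calls of named genes changed direction. For genes 205 values gained a call and 94 lost it, and for lists 104 and 45 did. With quantile normalization 34 of the 35 calls of named genes were kept, with centring, the dim filter, the trended robust model and array weights 35, with only the lines compared 32, with the replicate block 27 and without the 5 arrays that stood apart 25. The 10 lost there, among fewer arrays, kept their direction. Their log2 differences went in Fayoumi against broiler from 3.70 to 3.31 for FZD6 (adjusted p = 0.0891), -1.11 to -0.97 for LMO2 (0.129), -1.19 to -1.10 for BCKDHB (0.0503), 2.40 to 2.68 for BF2 (0.0589), 1.63 to 1.09 for TIMD4 (0.165), -4.75 to -4.60 for TNFRSF1B (0.336), -1.04 to -0.87 for TYMS (0.334) and 0.93 to 0.89 for VLDLR (0.142), and in Fayoumi against Leghorn from 4.36 to 3.94 for DIEXF (0.206) and 1.28 to 1.29 for HSD17B13 (0.0800). Signal over background limits what can be seen, since 36.1% of values sat at the lowest value of the table. The cause of the changes below was not tested, except that the dim filter tests fewer probe sets.

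Leaving out the dimmest probe sets gave 474 calls in Fayoumi against broiler and 407 in Fayoumi against Leghorn, and array weights gave 1319, 9 in Leghorn against broiler, 2042, and 5 in both leaner lines. Without the arrays labelled broiler 1 and Leghorn 2 the counts were 686, 661 and 544, with 241 in both leaner lines. With the 5 arrays that stood apart also as a covariate they were 623, 1263 and 806, with 283 in both, and without the muscle-rich array labelled Leghorn 1 as well 775, 1469 and 869, with 338 in both. The covariate alone gave 461 in Fayoumi against Leghorn. Without the 5 arrays that stood apart, Fayoumi against Leghorn gave 397, Leghorn against broiler 1 and both leaner lines 1. Leaving out 1 array at a time gave 148 to 613 in Fayoumi against broiler, 0 to 118 in Leghorn against broiler, 158 to 429 in Fayoumi against Leghorn and 0 to 59 in both leaner lines. In Fayoumi against broiler it gave 613 without the array labelled broiler 1, 170 without broiler 2, 171 without broiler 4, and 169, 148, 161 and 174 without Fayoumi 1, 2, 4 and 5. Without broiler 1, Leghorn against broiler gave 118 and both leaner lines 59, and without Leghorn 2, Fayoumi against Leghorn gave 429. After the 2 arrays were left out, leaving out 1 more gave 386 to 884, 461 to 780 and 363 to 661.

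With the replicate number as a block the counts were 141 in Fayoumi against broiler and 139 in Fayoumi against Leghorn, with 3 lists called in the latter. The 8 calls of named genes lost, at differences within 0.1 of those without it, were in Fayoumi against broiler TNFRSF1B (adjusted p = 0.0955), VLDLR (0.0800), BF2 (0.0913) and TIMD4 (0.0757), and in Fayoumi against Leghorn SOST (0.0538), DIEXF (0.130), HSD17B13 (0.118) and BCKDHB (0.0924). Without the arrays labelled broiler 1 and Leghorn 2 the replicate block gave 195 in Fayoumi and 248 in Leghorn against broiler, 214 in Fayoumi against Leghorn and 79 in both leaner lines, with 7 lists in Leghorn against broiler and 2 in Fayoumi against Leghorn. Pairing by number stays open, as the 5 arrays apart sway the test. Same-numbered arrays' deviations correlated at -0.815 to 0.623, over 0.1 in 4 of 16 pairs, with 4 of 32 best matches.

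The number of lists called was 4 in Fayoumi against broiler, 4 in Leghorn against broiler and 1 in Fayoumi against Leghorn. In Fayoumi against broiler it was 2 without the 5 arrays that stood apart, 0 with an estimated correlation and 0 by fry, and 3 to 6 when 1 array was left out. In Leghorn against broiler it was 7 without the arrays labelled broiler 1 and Leghorn 2, 7 with the covariate, 8 with both, 8 without the array labelled Leghorn 1 as well, 7 without the 5 arrays that stood apart, 0 with an estimated correlation, 0 by fry and 4 to 10 when 1 array was left out, with 10 without broiler 4 and 8 without Leghorn 2. In Fayoumi against Leghorn it was 2 with quantile normalization, 3 with centring, 3 with array weights, 2 with only the lines compared and 2 with the mean over a gene's probe sets. There it was also 2 without the arrays labelled broiler 1 and Leghorn 2, 3 with the covariate, 5 with both, 4 without the array labelled Leghorn 1 as well, 5 without the 5 arrays that stood apart, 0 with an estimated correlation, 0 by fry and 1 to 4 when 1 array was left out, with 4 without Fayoumi 3 or Leghorn 3, 3 without Leghorn 6, and 2 without broiler 1, Fayoumi 4 or Leghorn 1 or 2. Some lists not called with all arrays were called in the opposite direction of camera under an alternative. For the respiratory chain in Leghorn against broiler the median was 0.00987 with all arrays, 0.11 without broiler 2, -0.12 without the array labelled Leghorn 1 and -0.0894 with the covariate and without all 3 arrays named. For branched-chain amino acid catabolism it was 0.00436 there with all arrays and 0.0911 without the 5 arrays that stood apart, both positive, while camera's direction went from lower to higher. For skeletal muscle markers in Fayoumi against Leghorn it was -0.00270 with all arrays, -0.59 without Fayoumi 2, 1.09 without the array labelled Leghorn 1 and 1.04 with the covariate and without all 3 arrays.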

Other observations

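The genes in the first 2 paragraphs come from the fit without the arrays labelled broiler 1 and Leghorn 2, an alternative chosen after seeing the data, and were chosen after their values were seen. The arrays were left out because they lay with the other line, so the differences between broiler and Leghorn below may be too large, and 661 calls do not stand beside the 0 with the arrays as labelled as independent evidence. In that fit the cholesterol synthesis list fell in Leghorn against broiler, with a median of -1.12 over 17 members, 5 falling over all probe sets and 8 adjusted over the list alone (adjusted p = 1.52e-09, and adjusted p = 0.205 with an estimated correlation). SQLE was at 6.80 ± 0.24 (SD, n = 5) in Leghorn and 9.33 ± 0.61 (SD, n = 5) in broiler, 5.79-fold lower (SE 0.24, adjusted p = 0.000100). MSMO1, HSD17B7, NSDHL and DHCR7, all of the later steps of cholesterol synthesis, were 2.48-fold, 4.98-fold, 3.61-fold and 2.74-fold lower (adjusted p = 0.00149, 0.0236, 0.0302 and 0.00292). The fatty acid synthesis list fell too, with a median of -0.59 over 19 members, 3 falling over all probe sets and 6 falling with 1 rising adjusted over the list alone (adjusted p = 0.000212, and adjusted p = 0.542 with an estimated correlation). FADS2 and ACLY were 4.05-fold and 3.53-fold lower (adjusted p = 0.00378 and 0.00576), and FADS1, another desaturase, was at 4.64 ± 0.35 against 5.79 ± 0.49 (adjusted p = 0.0215), with 3 of 5 Leghorn arrays at values that another array shares. VLDLR was 1.54-fold lower in Leghorn (adjusted p = 0.0278), CPT1A 4.03-fold higher (adjusted p = 0.0374) and PLIN2 2.80-fold higher (adjusted p = 0.0220). The cholesterol synthesis list rose in Fayoumi against Leghorn, with a median of 0.71 and 3 members rising (adjusted p = 5.38e-05, and adjusted p = 0.705 with an estimated correlation).

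In that fit GZMA, a gene of cytotoxic lymphocytes, was higher in both leaner lines than in broiler, and so was BF2 on at least 1 probe set. GZMA was 14.1-fold higher in Leghorn and 11.5-fold higher in Fayoumi than in broiler (adjusted p = 0.000696 and 0.00127), and the probe set of BF2 with the largest difference was 50.8-fold and 32.8-fold higher (adjusted p = 4.87e-06 and 1.63e-05). In Leghorn against broiler MARCO was 4.17-fold higher (adjusted p = 0.00899), IFI27L2, an interferon-induced gene, 11.5-fold higher (adjusted p = 0.00182) and BLB1, a class II histocompatibility gene, 151-fold higher on 1 probe set (adjusted p = 3.29e-06), with 4 other probe sets not called in that direction. The macrophage and T lymphocyte lists rose in Leghorn, with medians of 0.28 and 0.15 (adjusted p = 0.00565 and 0.00583), and so did the epithelial list, with 0.22 (adjusted p = 0.0289), and with an estimated correlation adjusted p was 0.542 for each. The skeletal muscle list rose in the same fit, which holds the array labelled Leghorn 1, with a median of 1.98 (adjusted p = 0.000766, and adjusted p = 0.719 with an estimated correlation), and the cell cycle list fell, with -0.32 (adjusted p = 0.00320, and adjusted p = 0.557 with an estimated correlation). The epithelial list was highest on the arrays labelled Leghorn 6 and 3, at 1.29 and 1.14. CA5A, a mitochondrial carbonic anhydrase, was not above background on any of these Fayoumi or Leghorn arrays and at least 27.6-fold higher in broiler, and RHOG2, a small GTPase, was at 8.30 ± 0.84 in broiler and lower in Leghorn and Fayoumi (adjusted p = 6.36e-07 and 5.41e-07), where 3 of 5 and 5 of 5 arrays hold 1 shared value, 2.58, so no fold is given. UMPS, of pyrimidine synthesis, was at 8.15 ± 0.55 in Leghorn and 2.32 ± 0.07 in broiler (adjusted p = 1.62e-08) and above background on 2 of 5 broiler arrays. ASPH, an aspartate hydroxylase, was 262-fold lower (adjusted p = 4.59e-05). Such folds hold for 1 probe set of a gene. For called differences of at least 3 on the log2 scale in Leghorn against broiler in this fit, other probe sets mostly did not follow. The ratio of their difference to the called one had a median of 0.0441 over 63 pairs, with 16 called in the same direction. In Fayoumi against broiler adiponectin was 2.44-fold lower (adjusted p = 0.0274) and EHHADH 2.94-fold lower (adjusted p = 0.0233). With the 5 arrays that stood apart as a covariate these 2 calls were lost, with log2 differences of -1.29 and -1.56 smaller by 0.29 and 0.41 (adjusted p = 0.126 and 0.0987), as with the replicate block (adjusted p = 0.118 and 0.160), and without the array labelled Leghorn 1 as well adiponectin was called again (adjusted p = 0.00335) and EHHADH was not (adjusted p = 0.0793). Over all chicken probe sets of this fit 6.72%, 2.42% and 4.64% had no overlap between arrays in Fayoumi against broiler, Leghorn against broiler and Fayoumi against Leghorn, where chance gives 0.794%, and leaving out arrays that lay with the other line raises the share in Leghorn against broiler by its choice.

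Other splits of the arrays as labelled were counted, 100 drawn for each comparison with the real one included, in tests written before the result was seen. Chance can be excluded for the 269 probe sets in Fayoumi against broiler, where 2 of 100 splits gave as many and the highest other gave 646, with the array labelled broiler 1 placed with the Fayoumi arrays. It can be excluded for the 236 in Fayoumi against Leghorn, where 1 split, the real one, gave as many and the highest other gave 1. For Leghorn against broiler the real count was 0, which every split reaches, so the splits decide nothing there. The highest was 7008, from a split with all 5 arrays that stood apart on one side, which points to a structure of the samples. For the lists chance cannot be excluded in any comparison. In Fayoumi against broiler 41 splits gave 4 or more with a highest other of 8, in Leghorn against broiler 70 gave 4 or more with a highest other of 13, and in Fayoumi against Leghorn 100 gave 1 or more with a highest other of 15.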
